A study of Mus musculus with 7 samples.

How the data were processed

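Single-nucleus RNA sequencing of mouse precision-cut liver slices was analysed from 7 libraries: day 0, and untreated and IL-4-treated slices on days 1, 3 and 5. The deposited values were raw UMI counts per gene and barcode, made by the authors with 10x Genomics matrix software of version 3.1.0 in format version 2, per the file headers. Per the file headers, each matrix listed 6794880 barcodes and 31053 mouse genes and was not reduced to nuclei. The other deposited files held barcode and gene names and no measurement. The submitters' processing notes name Seurat version 3 and the human build GRCh38, while the gene identifiers in the files were mouse; the aligner and the counting of intronic reads are not given in the sources used here.

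From these counts, nuclei were chosen per library with a minimum of UMIs equal to the 99th percentile of the 6000 deepest barcodes divided by 10, the capture target per the labels, and never under 500. The minimum came to 1859 UMIs on day 0, 5661 and 6054 (untreated and IL-4) on day 1, 1979 and 2214 on day 3, and 2215 and 1803 on day 5. At least 300 genes and under 5% mitochondrial UMIs were also needed, and 16258 barcodes passed. Scrublet, with its own threshold per library, called 648 doublets, 341 of them in the untreated and 278 in the IL-4 library of day 3 and at most 13 in any other library. That left 15610 nuclei. Barcodes with 10 to 100 UMIs were taken as empty and gave the level of free RNA.

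Counts were scaled per nucleus and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave 30 Leiden clusters at resolution 1 (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9; figures with matplotlib 3.10.9). Clusters were named from fixed marker lists as hepatocyte-like, cholangiocyte-like, endothelial-like, mesenchymal-like, macrophage-like, B-like, and T-like or NK-like, and the rest were left unnamed as epithelial or mixed. Libraries were not aligned to each other, so that a class may hold different clusters in different libraries. Shares carry 95% Clopper-Pearson intervals.

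For the tests, counts were summed per library over the nuclei of a class, for libraries with at least 20 such nuclei. In R 4.3.3 with edgeR 4.0.16, sums were scaled by trimmed means, genes were filtered by expression, and a quasi-likelihood model with a term for each day and 1 for IL-4 was fitted. It leaves 2 residual degrees of freedom with 3 days and 1 with 2 days. Genes called had a Benjamini-Hochberg adjusted p under 0.05, and fold changes are log2 of IL-4 over untreated. CPM of classes use the scaled library sizes, and CPM of empty barcodes plain totals. Per-day ratios carry exact 95% counting intervals, and a side with 0 counts was set to 3 counts. Fixed gene lists, 27 in number, were tested with camera in limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were measured. Members were also adjusted over the list alone. In the hepatocyte-like class, with enough nuclei in 1 cultured pair only, list medians were set against 10000 random lists matched on size and expression (seed 0). For cell cycle shares every nucleus was thinned to 1800 UMIs, and a nucleus counted with at least 2 UMIs of the list.

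The genes named in the text follow a fixed rule: up to 4 members of each list with the largest change among those past the threshold; 10 genes per direction with the largest change past the threshold, the same sign on every day and at least 50 CPM in the higher arm, without predicted, mitochondrial and ribosomal genes; where fewer than 5 passed, the 10 genes with the largest smallest change over days and at least 50 counts; Il4ra, Il13ra1, Il2rg and Stat6; and the 5 most abundant genes of the empty barcodes. Stab2 and Alb were named besides, as members that did not follow their lists. Tests, filters, gene lists, the rule and most alternative settings were set before the data were examined. Tests of the cholangiocyte-like class and of the epithelial clusters, the culture contrasts of endothelial-like and macrophage-like nuclei, the uniform minimum of 2000 UMIs, the doublet score of 0.25, the reassigned mixed clusters and the removal of Xist-positive day 3 nuclei were added after the data had been seen.

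The test was tried on simulated counts with 200 changed genes, 100 at each size. It recovered 38% of 2-fold and 86% of 4-fold changes for macrophage-like nuclei (12349 genes), 52% and 89% for endothelial-like (12969), 9% and 66% for mesenchymal-like (12669), 55% and 99% for cholangiocyte-like (10458), 45% and 93% for the epithelial clusters (13009) and 57% and 92% for all nuclei (20191). Of the unchanged genes at most 9 were called. Simulated genes were drawn independently, with a spread set by expression level alone and the same IL-4 effect on each day. The rates hold for that setting and were not shown for the real counts. Alternatives were DESeq2 1.42.0, other scaling, no filter, no term for day, leaving out each day, the 200 most abundant genes of empty barcodes left out, doublets kept, a mitochondrial ceiling of 1% and the deepest 2000 nuclei per library.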

Results

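Mouse precision-cut liver slices, thin sections of living liver kept in culture with their cell types in place, were sampled by single-nucleus RNA sequencing on day 0 and after 1, 3 and 5 days of culture with or without interleukin-4 (IL-4). IL-4 is a type 2 cytokine that signals through Il4ra and the transcription factor Stat6 and drives alternative activation of macrophages. From the title of the series, the question was whether it reprogrammes the cells of cultured liver towards regeneration. There were 7 libraries, 1 for each day and treatment, so no group had a replicate. Total unique molecular identifiers (UMIs) were 22584693 on day 0, 54511227 and 60114588 in the untreated and IL-4 libraries of day 1, 13502901 and 21353826 on day 3, and 23731515 and 19096219 on day 5. After filtering, 3127 nuclei were kept on day 0, 2582 untreated and 2440 IL-4 nuclei on day 1, 925 and 2094 on day 3, and 2310 and 2132 on day 5. Their median depths were 4468 UMIs on day 0, 11877 and 11645 on day 1, 4375 and 5226.5 on day 3, and 7259.5 and 6336.5 on day 5. The day 1 slices also differed in sex from the others: 92.2% and 86.1% of untreated and IL-4 nuclei had Xist and no Y-linked transcripts on day 1, against 0% on days 0 and 5 and at most 2.05% on day 3, so that day 1 and sex could not be separated.

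By the names given to clusters, culture replaced a hepatocyte-rich tissue by one of biliary, unnamed epithelial, endothelial, mesenchymal and macrophage nuclei. The unnamed epithelial clusters 23, 24 and 28 held Hnf4a at 93.6, 125 and 142 CPM (plain totals). Hepatocyte-like cluster 16, mostly of day 1, held it at 27.5 and cholangiocyte-like cluster 9 at 116 CPM. Hepatocyte-like clusters 1, 3 and 5, nearly all of day 0, held it at 526, 600 and 477 CPM. The unnamed epithelial clusters held 179 of 925 untreated nuclei on day 3 and 194 of 2310 on day 5. Most nuclei of both libraries were thus of other classes under either naming. The size of the fall in hepatocyte-like nuclei depends on which clusters were so named. On day 1 cluster 16 held 492 of the 1207 untreated hepatocyte-like nuclei. Hepatocyte-like nuclei made up 89.5% of nuclei on day 0 (95% Clopper-Pearson interval 88.4 to 90.6) and 46.7% (44.8 to 48.7) of untreated nuclei on day 1. On day 3 they made up 0.541% (0.176 to 1.26) of untreated nuclei, and on day 5 there was 1 of 2310. Cholangiocyte-like nuclei, which carry markers of the bile duct lining, were 0.288% on day 0, 1.16% of untreated nuclei on day 1, 21.4% on day 3 and 59.3% on day 5 (on day 1, 2.40% at a minimum of 2000 UMIs in every library). Mesenchymal-like nuclei rose from 2.37% on day 0 to 20.4% of untreated nuclei on days 3 and 5, after 0.581% on day 1. That low share rests on mixed cluster 13 being left unnamed: 15 of 2582 nuclei were mesenchymal-like on day 1, and 246 with that cluster counted. B-like nuclei were 5.34% and T-like or NK-like nuclei 1.98% of untreated nuclei on day 1, against 0.224% and 0.160% on day 0, 0.541% and 0 of 925 on day 3, and 0.130% and 0 of 2310 on day 5. Day 1 thus stood apart. On that day their median level of the hepatocyte markers was 92.5% and 82.4% of that of hepatocyte-like nuclei, untreated. Clusters with markers of several types, left unnamed, held 32.5% of untreated and 43.0% of IL-4 nuclei on day 1, and at most 0.621% in the other libraries. Shares are of the nuclei kept, the intervals and floors cover counting error only, and no test between single libraries was possible. The libraries also differed in depth, in the minimum of UMIs per nucleus and in the doublets called, which were 26.9% of nuclei in the untreated and 11.7% in the IL-4 library of day 3 and at most 0.606% elsewhere.

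With IL-4, endothelial-like nuclei took a larger share on both later days and mesenchymal-like nuclei a smaller one. Endothelial-like nuclei were 18.4% (15.9 to 21.03) of untreated and 33.2% (31.2 to 35.3) of IL-4 nuclei on day 3, and 7.23% (6.21 to 8.36) and 15.2% (13.7 to 16.7) on day 5, after 6.93% and 7.30% on day 1. Those day 1 shares depend on the minimum of UMIs: at 2000 UMIs in every library they were 12.4% and 11.7%, and in the deepest 2000 nuclei 4.25% and 5.30%. Mesenchymal-like nuclei were 20.4% (17.9 to 23.2) and 8.36% (7.21 to 9.63) on day 3, and 20.4% (18.8 to 22.1) and 8.30% (7.16 to 9.56) on day 5. A group of unnamed epithelial clusters, with markers of both hepatocytes and bile duct cells, held 19.4% and 24.5% on day 3 and 8.40% (7.30 to 9.60) and 18.6% (16.99 to 20.3) on day 5. Cholangiocyte-like nuclei were 21.4% and 9.12% on day 3, and 59.3% and 51.9% on day 5. Macrophage-like nuclei were 19.03% and 21.8% on day 3, and 4.42% and 5.39% on day 5. Hepatocyte-like nuclei were 35.5% (33.6 to 37.4) with IL-4 on day 1, against 46.7% untreated. Cluster 16 held 701 of these 865 IL-4 nuclei and 492 of the 1207 untreated ones. It held Hnf4a at 27.5 and Alb at 576 CPM (plain totals). B-like cluster 8 held them at 34.4 and 598 CPM, and T-like or NK-like cluster 12 at 39.3 and 553 CPM. Both day 1 shares thus depend on the name given to cluster 16. On day 3 hepatocyte-like nuclei were 1.96%, against 0.541% untreated, and with doublets kept the untreated share was 1.34%. Without the nuclei of the IL-4 library that had Xist and no Y-linked transcripts, its share was 0.341%, below the untreated one. On day 5 they were 0 of 2132, which allows up to 0.173%.

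**Figure D1:**
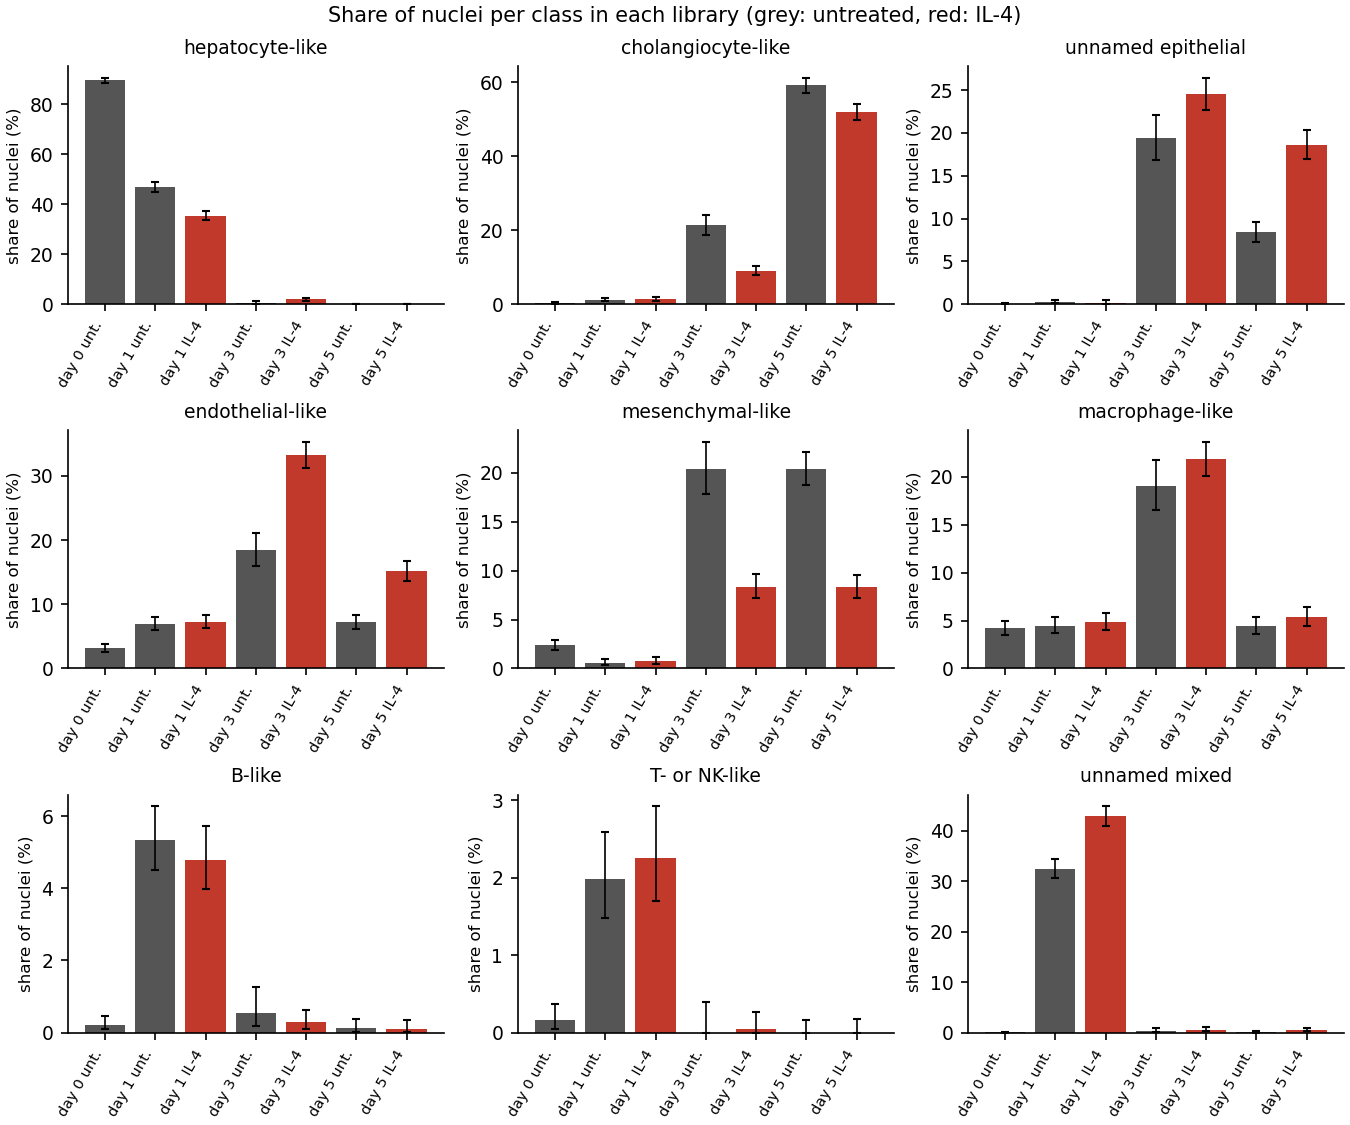
Share of kept nuclei in each class (percent, bars from 0) for the 7 libraries, with 95% Clopper-Pearson intervals. Hepatocyte-like nuclei make up 89.5% of day 0 and at most 1.96% of any library of days 3 and 5.

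Macrophage-like nuclei showed the broadest set of alternative activation genes. The arginine transporter Slc7a2 (ENSMUSG00000031596) rose by a log2 fold change of 5.11 (SE 0.29, adjusted p = 0.000114), the cholesterol hydroxylase Ch25h (ENSMUSG00000050370) by 4.98 (SE 0.28, adjusted p = 0.000114) and Pdcd1lg2 (ENSMUSG00000016498), which encodes the checkpoint ligand PD-L2, by 4.70 (SE 0.35, adjusted p = 0.000304). The eosinophil chemokine Ccl24 rose by 4.44 (SE 0.61, adjusted p = 0.00459), the chemokine Ccl8 by 5.76 and the mannose receptor Mrc1 by 2.23. Chil3, a chitinase-like protein of alternatively activated macrophages, had 0 counts in the 3 untreated libraries and 6199 with IL-4, at least 1184-fold higher against a floor of 3 counts over the group. Of these, 5 counts were of day 1, 2673 of day 3 and 3521 of day 5. Its 4.08 CPM on day 1 lay below the 54.1 CPM of the empty barcodes, so the rise rests on days 3 and 5. Retnla (0 and 332 counts) was at least 63.4-fold higher and the lectin Mgl2 (0 and 125 counts) at least 23.9-fold higher. Counts of Chil3 and its close relative Chil4 cannot be told apart with certainty, since reads of such paralogs can be split between them.

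Of the 22 measured members of the alternative activation list in macrophage-like nuclei, 18 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 6.81e-62, and adjusted p = 0.191 with an estimated correlation). Arginase 1 (Arg1) rose by 3.72 (adjusted p = 0.0133) and the receptor chain Il4ra by 1.51 (adjusted p = 0.0124), and both calls were lost without the day 5 libraries, at 3.94 (adjusted p = 0.0839) and 1.22 (adjusted p = 0.0965). Over all alternatives the adjusted p of Arg1 ranged from 3.73e-76 to 0.221 and that of Il4ra from 4.76e-12 to 0.313. The other receptor chain, Il13ra1, differed by 0.23 (adjusted p = 0.684) and Stat6 by -0.31 (adjusted p = 0.477). Among the genes of Kupffer cells, the resident macrophages of the liver, 7 of 15 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 4.97e-08, and adjusted p = 0.328 with an estimated correlation). The apoptosis inhibitor Cd5l fell by 4.35 (SE 0.55, adjusted p = 0.00322), the lectin Clec4f by 2.50 (SE 0.31, adjusted p = 0.00286) and Spic, a transcription factor of iron-recycling macrophages, by 2.26. The scavenger receptor Marco fell by 3.93 (adjusted p = 0.0165); its log2 fold change was -6.27 (adjusted p = 6.13e-06) without the day 1 libraries and -3.55 (adjusted p = 0.0663) without those of day 5, in a range of adjusted p from 3.79e-58 to 0.673.

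Other lists moved with IL-4 in macrophage-like nuclei as well. Of 21 matrix and fibrogenesis genes, 8 fell and 1 rose (13 and 2 adjusted over the list alone; camera adjusted p = 2.36e-07, and adjusted p = 0.569 with an estimated correlation). The collagen gene Col3a1 fell by 3.52 (SE 0.30, adjusted p = 0.000638), and the gene that rose was Postn, for the matricellular protein periostin, by 5.82 (SE 0.30, adjusted p = 0.000114). Col3a1 was also lower with IL-4 in the empty barcodes, at 50.5, 219 and 1071 CPM (counts scaled to a common library size) on days 1, 3 and 5 against 151, 1628 and 4365 untreated. Of 13 regenerative growth factors and receptors, 3 rose and 1 fell (4 and 3 adjusted over the list alone), and the list as a whole did not pass the test (camera adjusted p = 0.684). The EGF receptor ligand Hbegf rose by 3.04 (SE 0.22, adjusted p = 0.000273) and the hepatocyte growth factor gene Hgf fell by 2.42 (SE 0.27, adjusted p = 0.00177). Hgf was also lower in the empty barcodes, at 14.9, 45.2 and 11.5 CPM with IL-4 against 84.7, 79.3 and 65.0 untreated. Of 16 hypoxia and glycolysis genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 2.87e-05, and adjusted p = 0.660 with an estimated correlation), among them hexokinase 2 (Hk2) by 1.01. The integrin Itgax rose by 2.22, and the inhibitory Fc receptor Fcgr2b by 4.09.

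The test in macrophage-like nuclei compared the 3 IL-4 libraries with the 3 untreated ones in a model with a term for day (edgeR quasi-likelihood, Benjamini-Hochberg). It called 441 genes higher and 285 lower, 726 of 12504, and 2467 had an unadjusted p under 0.05. Different clusters held the class in each group: cluster 10 the untreated nuclei (113, 170 and 102) and cluster 25 the IL-4 nuclei (112, 451 and 115 on days 1, 3 and 5). The count was 290 without the day 5 libraries and 272 with the mixed day 1 clusters 17 and 13 counted as macrophage-like and mesenchymal-like, when the calls of Il4ra and Fcgr2b were lost. Without a term for day it was 49. Here and below, p-values measure only the spread of the IL-4 difference between these libraries, which come 1 per group. Every tested gene said to rise or fall with IL-4 had the same sign on each day compared.

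**Figure D2:**
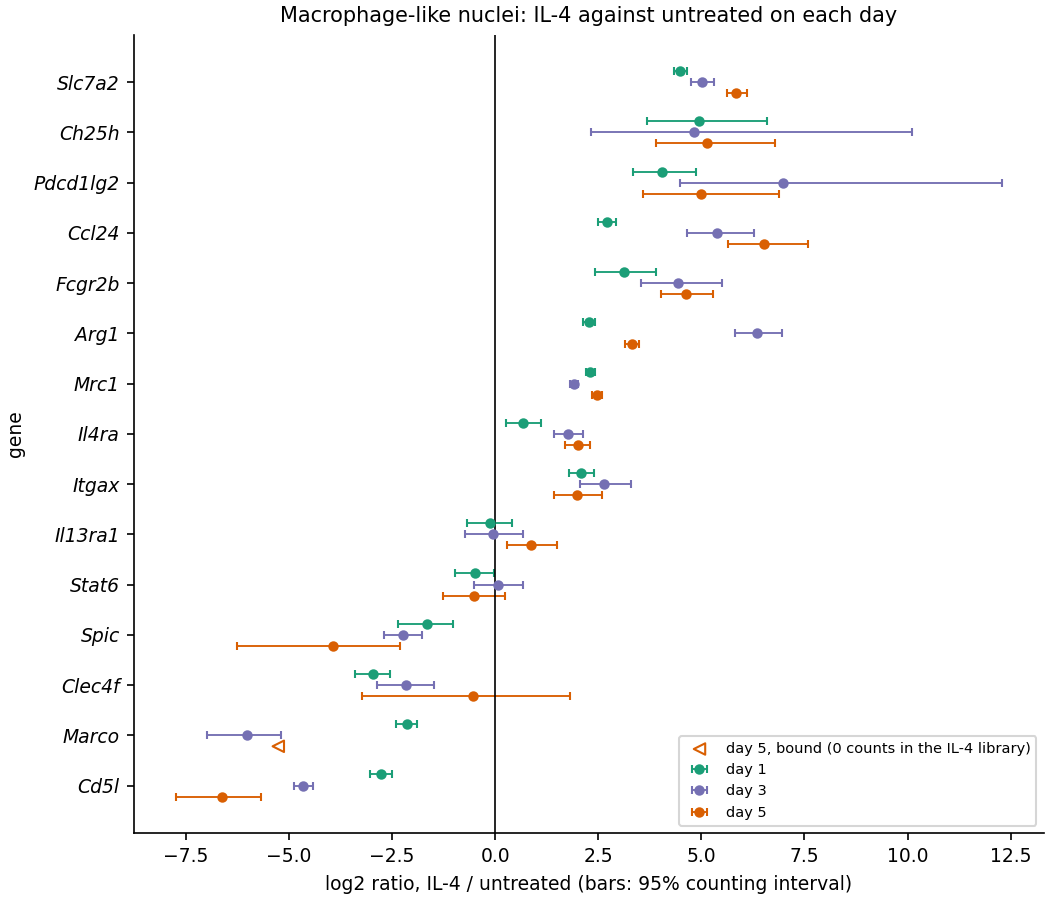
Log2 ratio of IL-4 to untreated macrophage-like nuclei for 15 genes on days 1, 3 and 5, with 95% counting intervals; the value of Marco on day 5 is a bound from 0 counts. Slc7a2, Ch25h and Pdcd1lg2 lie above 4 on each day, and Cd5l lies below -2.7 on each day.

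In endothelial-like nuclei the neuropeptide gene Nts (ENSMUSG00000019890) rose by 6.25 (SE 0.39, adjusted p = 0.000507), the guidance cue Sema3a (ENSMUSG00000028883) by 4.12 (SE 0.21, adjusted p = 0.000345) and the serotonin receptor Htr2a by 5.07. The carbonic anhydrase Car4, a capillary marker, had 0 counts untreated and 531 with IL-4, at least 93.3-fold higher, and the neuropeptide Gal went from 2 to 399 counts, a log2 ratio of 6.72 (counting interval 4.85 to 9.77). Of 16 sinusoidal identity genes, 8 fell and 0 rose (13 and 1 adjusted over the list alone; camera adjusted p = 3.62e-10, and adjusted p = 0.498 with an estimated correlation). Mrc1, which rose in macrophage-like nuclei, fell here by 3.29 (SE 0.46, adjusted p = 0.00733), and the coagulation factor gene F8 fell by 3.14 (SE 0.43, adjusted p = 0.00708). Hgf, which sinusoidal cells supply to hepatocytes, fell by 4.13 (SE 0.46, adjusted p = 0.00487), the lectin Clec1b by 3.68 and the integrin Itga8 by 4.67. The sinusoidal gene Stab2 was not called, at 0.49 (adjusted p = 0.322).

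Of 14 genes of capillary and activated endothelium, 5 rose and 2 fell in endothelial-like nuclei (6 and 3 adjusted over the list alone; camera adjusted p = 0.0180, and adjusted p = 0.558 with an estimated correlation). The angiogenic ligand Pgf rose by 2.90 (SE 0.40, adjusted p = 0.00715) and the tip cell gene Esm1 by 1.97 (SE 0.21, adjusted p = 0.00416). Of 17 hypoxia and glycolysis genes, 5 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 5.16e-09, and adjusted p = 0.613 with an estimated correlation), with the vasodilator gene Adm up by 3.29 (SE 0.31, adjusted p = 0.00245). Of 17 alternative activation genes, 5 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00143, and adjusted p = 0.558 with an estimated correlation). The monocyte chemokine Ccl2 rose by 1.91 and the HGF receptor Met by 1.63. In the empty barcodes Ccl2 rose too, to 2829, 2406 and 2007 CPM with IL-4 on days 1, 3 and 5 against 692, 828 and 618 untreated. Its rise here and in the classes below was not told from one in free RNA. The Kupffer cell list fell too, with 3 of 10 members lower and 0 higher (5 and 0 adjusted over the list alone; camera adjusted p = 0.000589, and adjusted p = 0.558 with an estimated correlation). Kupffer cell transcripts were lower in the empty barcodes as well, with Cd5l at 46.2, 26.6 and 2.09 CPM with IL-4 on days 1, 3 and 5 against 114, 350 and 92.2 untreated. A fall in free RNA was not told from one in endothelial-like nuclei. Il4ra differed by -0.02 (adjusted p = 0.965), Il13ra1 by -0.37 (adjusted p = 0.580) and Stat6 by 0.10 (adjusted p = 0.840). In all, 374 genes were higher and 357 lower, 731 of 13062, and the count was 139 without the day 3 libraries and 1 without a term for day, where DESeq2 with that term called 441. Cluster 11 held the untreated nuclei and those of day 1 with IL-4, cluster 20 held 686 IL-4 and 32 untreated nuclei of day 3, and cluster 29 held 302 IL-4 nuclei of day 5.

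Cholangiocyte-like nuclei held the chitinase-like gene Chil4 (ENSMUSG00000063779) at 4679, 4972 and 7928 CPM with IL-4 on days 1, 3 and 5, against 4.54, 34.8 and 0.218 CPM untreated, a log2 fold change of 10.17 (SE 0.92, adjusted p = 5.18e-05). In the same IL-4 libraries it was at 944, 4844 and 42965 CPM in the empty barcodes. Endothelial-like nuclei held it at 36.9, 75.6 and 340 CPM (plain totals). Slc7a2 rose by 5.43 (SE 0.25, adjusted p = 2.24e-07), the cytokine Il24 by 6.83 (SE 0.40, adjusted p = 1.75e-06) and the prostaglandin synthase Ptgs2 (ENSMUSG00000032487) by 3.72 (SE 0.29, adjusted p = 2.14e-05). Of 13 alternative activation genes, 8 rose and 0 fell (the same numbers adjusted over the list alone; camera adjusted p = 1.19e-16, and adjusted p = 0.520 with an estimated correlation). Of 16 hypoxia and glycolysis genes, 9 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 7.44e-13, and adjusted p = 0.520 with an estimated correlation). Of 7 genes of classical inflammation, 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 6.75e-13, and adjusted p = 0.520 with an estimated correlation), among them Ccl2 by 2.20 and the neutrophil chemokine Cxcl2 by 2.06.

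Of 16 stress and unfolded protein genes in cholangiocyte-like nuclei, 5 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 1.28e-05, and adjusted p = 0.520 with an estimated correlation), with the chaperone Hspa5 up by 1.26 (SE 0.19, adjusted p = 0.00185). The keratins Krt8 and Krt18 rose by 1.03 and 0.79. Lower with IL-4 were the sulfotransferase Chst9 by -3.79 (SE 0.35, adjusted p = 6.91e-05), the acyl-CoA synthetase Acss3 by -3.32 (SE 0.24, adjusted p = 8.58e-06) and the guidance ligand Slit2 by -3.09. Il4ra rose by 1.29 (adjusted p = 0.0118), which was 0.64 (adjusted p = 0.514) without the day 5 libraries, the upper end of a range of adjusted p from 3.01e-06, and the call was also lost with DESeq2. Il13ra1 differed by 0.04 (adjusted p = 0.973) and Stat6 by -0.14 (adjusted p = 0.861). The test called 329 genes higher and 231 lower, 560 of 10874, and 351 without the day 5 libraries and 6 without a term for day. On day 1 the class held 30 untreated and 35 IL-4 nuclei. On day 5 cluster 9 held 1209 of the untreated nuclei and cluster 21 held 1006 of the IL-4 nuclei.

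The unnamed epithelial clusters 23, 24 and 28 showed several of the same genes with IL-4. Chil4 had 0 counts untreated and 45898 with IL-4 over days 3 and 5, at least 6807-fold higher. Ptgs2 rose by 5.59 (SE 0.30, adjusted p = 9.52e-06), Slc7a2 by 4.02 (SE 0.42, adjusted p = 0.000433), the oxygen sensor Egln3 by 4.78 (SE 0.20, adjusted p = 3.01e-06) and Il4ra by 2.03 (SE 0.17, adjusted p = 0.000116). Of 14 alternative activation genes, 9 rose and 1 fell (the same numbers adjusted over the list alone; camera adjusted p = 2.04e-18, and adjusted p = 0.743 with an estimated correlation). Of 14 hepatocyte identity genes, 3 fell and 2 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.0230 for lower, and adjusted p = 0.799 with an estimated correlation). Lower outside that list were Mug1 and Mug2, which are paralogs and uncertain for that reason, by -6.10 and -6.35, the growth factor binding protein Igfbp1 by -4.09 (SE 0.29, adjusted p = 5.76e-05), and the oncofetal gene Gpc3 by -4.08. The keratins Krt8 and Krt19 rose by 2.13 and 2.18. Of 11 bile acid genes, 6 fell and 0 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.000122, and adjusted p = 0.743 with an estimated correlation), among them the phospholipid exporter Abcb4 by 2.96 and Nr0b2, the repressor of bile acid synthesis, by 2.58. Of 16 YAP and TEAD targets, 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.000115, and adjusted p = 0.743 with an estimated correlation), with Ankrd1 up by 2.16. Of 9 xenobiotic metabolism genes, 3 fell and 0 rose (3 and 1 adjusted over the list alone); their median was 0.03 and their mean -0.59, with the test lower (camera adjusted p = 0.0396, and adjusted p = 0.799 with an estimated correlation).

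Of 20 genes of the G2 and M phases, 12 rose and 0 fell in the epithelial clusters (17 and 0 adjusted over the list alone; camera adjusted p = 6.37e-13, and adjusted p = 0.743 with an estimated correlation). Topoisomerase Top2a rose by 2.48 (SE 0.35, adjusted p = 0.00209) and the chromosomal passenger gene Birc5 by 1.91 (SE 0.35, adjusted p = 0.00776), and both calls were lost with a doublet score of 0.25 in every library, that of Birc5 also with doublets kept. Of 19 S phase genes, 6 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 6.04e-07, and adjusted p = 0.743 with an estimated correlation). Nuclei with at least 2 UMIs of the G2 and M list after thinning to 1800 UMIs were 13.97% (9.25 to 19.9) untreated and 32.1% (28.1 to 36.3) with IL-4 on day 3, and 2.58% (0.842 to 5.91) and 14.9% (11.5 to 18.8) on day 5. Unthinned, the shares were 36.3% and 61.3% on day 3, and 26.8% and 33.5% on day 5, at median depths of 6184 and 7380.5 UMIs on day 3 and 11042.5 and 8340.0 on day 5. Endothelial-like nuclei, at median depths of 3647 and 4145.5 UMIs on day 3 and 7098 and 6279 on day 5, gave 1.18% and 3.45% on day 3, and 6.59% and 1.24% on day 5. Cholangiocyte-like and epithelial nuclei pooled gave 17.8% (14.05 to 22.01) and 35.2% (31.6 to 38.8) on day 3, and 10.9% (9.38 to 12.5) and 11.5% (9.93 to 13.2) on day 5, with unthinned shares of 34.0% and 59.7%, and 28.7% and 23.7%. Cholangiocyte-like nuclei alone gave 21.2% and 43.5% on day 3, and 12.1% and 10.3% on day 5, with unthinned shares of 31.8% and 55.5%, and 28.999% and 20.2%, at median depths of 4159 and 4775 UMIs, and 6491 and 5683. No difference between the 2 groups was tested. Cluster 24, led by genes of mitosis, was counted with the epithelial clusters, and cluster 18, led by them as well, with cholangiocyte-like nuclei. The G2 and M calls in the epithelial clusters thus depend on this grouping, made after the clusters were seen.

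These 3 clusters were put together after the clusters had been seen, and the test covers days 3 and 5 with 1 residual degree of freedom. It called 861 genes higher and 540 lower, 1401 of 13235, and 0 without a term for day (edgeR; 1041 at an unadjusted p under 0.05, and DESeq2 with that term called 539). Cluster 23 held 161 and 192 untreated nuclei of days 3 and 5, cluster 28 held 272 and 341 IL-4 nuclei, and genes of mitosis led cluster 24, which held 164 and 54 IL-4 and 18 and 2 untreated nuclei.

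**Figure D3:**
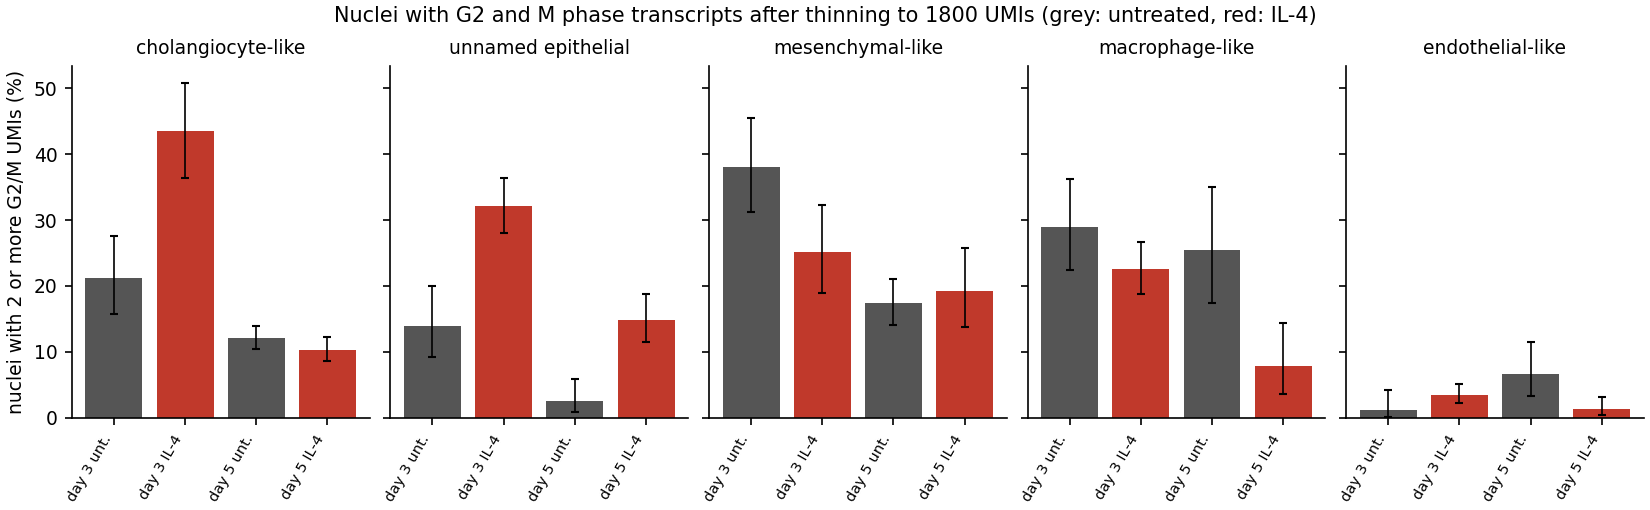
Share of nuclei (percent) with at least 2 UMIs of the G2 and M list after thinning every nucleus to 1800 UMIs, for 5 classes on days 3 and 5, untreated and IL-4, with 95% Clopper-Pearson intervals. In the epithelial clusters the share is 13.97% untreated and 32.1% with IL-4 on day 3, and 2.58% and 14.9% on day 5.

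Mesenchymal-like nuclei were tested on days 3 and 5. The cytokine gene Il11 (ENSMUSG00000004371), which acts in fibrosis, rose by 5.89 (SE 0.60, adjusted p = 0.0297), the decoy receptor Il13ra2 (ENSMUSG00000031289) by 5.54 (SE 0.37, adjusted p = 0.0170) and the kinase Alpk2 by 6.27 (SE 0.30, adjusted p = 0.00667). Ptgs2 rose by 3.54 (SE 0.28, adjusted p = 0.0203), Ccl2 by 2.20 (Ptgs2 in the empty barcodes went from 57.5 to 532 CPM on day 3 and from 210 to 3100 CPM on day 5), and the EGF receptor ligands Areg and Ereg by 3.28 (SE 0.39, adjusted p = 0.0409) and 2.90 (SE 0.23, adjusted p = 0.0203). Of 10 genes of classical inflammation, 2 rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 6.86e-07, and adjusted p = 0.663 with an estimated correlation). Of 16 growth factors and receptors, 3 rose and 0 fell (4 and 4 adjusted over the list alone), and the list did not pass the test (camera adjusted p = 0.104); the angiogenic factor Vegfa was the other that rose, by 2.18. Of 22 matrix genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 1.27e-05, and adjusted p = 0.687 with an estimated correlation), among them the protease inhibitor Timp1 by 2.37 and the matrix-binding protein gene Thbs1 by 1.45. Of 17 alternative activation genes, 4 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 2.40e-15, and adjusted p = 0.663 with an estimated correlation), among them Slc7a2 by 2.58. Lower were the fibrillin gene Fbn2 by -2.37, the bile acid receptor Nr1h4 by -2.38 and the Wnt target Lgr5 by -4.81. Il4ra differed by -0.22 (adjusted p = 0.833), Il13ra1 by -0.26 (adjusted p = 0.734) and Stat6 by -0.02 (adjusted p = 0.997). The test called 81 genes higher and 29 lower, 110 of 12930, with 1665 at an unadjusted p under 0.05. With the 200 most abundant genes of empty barcodes left out it called 18, and the calls of Il11, Areg, Timp1, Thbs1, Fbn2, Nr1h4 and Lgr5 were lost. Their fold changes stayed nearly the same (Il11 5.89, Areg 3.28, Lgr5 -4.80), with adjusted p of 0.0600 or more. It called 558 with doublets kept, and without a term for day edgeR called 0 (468 at an unadjusted p under 0.05, and DESeq2 with that term called 106). Cluster 22 held most nuclei, and cluster 27 held 178 untreated and 13 IL-4 nuclei of day 5.

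Hepatocyte-like nuclei could be compared on day 1 only, 865 with IL-4 and 1207 untreated, as values of 2 libraries with no test. Slc7a2 had a log2 ratio of 2.77 (95% counting interval 2.71 to 2.83), Ch25h of 2.99 (1.96 to 4.20), Ptgs2 of 3.82 (3.18 to 4.52) and the STAT-induced inhibitor Cish of 2.39 (2.19 to 2.60). In the empty barcodes of day 1 Ch25h went from 52.2 to 322 CPM and Ptgs2 from 27.3 to 199 CPM. Free RNA was not told from expression in these nuclei. Lower were the urinary protein Mup20 at -4.24 (-4.62 to -3.89), the monooxygenase Fmo5 at -4.20 (-4.42 to -3.99), Nr0b2 at -3.17 (-3.98 to -2.46), Abcb4 at -2.71 (-2.83 to -2.60) and the hepatocyte transcription factor Hnf4a at -1.22 (-1.40 to -1.05). Of 18 acute phase genes 16 were lower, with a median of -0.69, and the serum amyloid gene Saa3 was at -1.88 (-1.97 to -1.79) while the iron hormone gene Hamp was at 1.21 (1.13 to 1.30). These changes were not those of hepatocyte-like nuclei alone: Saa3 went from 266 to 77.5 CPM in B-like and from 209 to 59.5 CPM in T-like or NK-like nuclei, and in the empty barcodes from 829 to 256 CPM. Hp went from 6190 to 1928 and Hamp from 215 to 510 CPM there. Of 18 identity genes 14 were lower (median -0.77), of 17 bile acid genes 14 (median -0.81) and of 22 xenobiotic metabolism genes 18 (median -0.73), and each of these 4 medians lay below all of 10000 random lists matched on size and expression. Of 15 alternative activation genes 13 were higher (median 1.01) and of 19 S phase genes 18 (median 0.62), both medians above all random lists, with the replication gene Mcm5 at 1.46. The summed S phase list went from 246 to 324 CPM in hepatocyte-like nuclei (plain totals). It also rose in T-like or NK-like (287 to 398 CPM), B-like (288 to 323) and cholangiocyte-like nuclei (833 to 1065). Endothelial-like (334 to 317) and macrophage-like nuclei (302 to 299) showed no rise. Of 18 genes of lipid and sterol synthesis 11 were higher (median 0.04, percentile 60.5), and the albumin gene Alb was at 0.58 (0.54 to 0.62). Of 13 G2 and M genes 6 were higher (median -0.01, percentile 60.2). Il4ra was at 0.27 (0.10 to 0.45), Il13ra1 at -0.03 (-0.16 to 0.09) and Stat6 at 0.06 (-0.13 to 0.24). Clusters 14 and 16 held 624 and 492 of the untreated nuclei and 58 and 701 of the IL-4 nuclei. Neither had a gene of the fixed hepatocyte marker list among its 10 leading genes. Cluster 14 nonetheless held Fgb at 1784 and Apob at 411 CPM (plain totals), and cluster 16 at 781 and 255 CPM. B-like cluster 8 held them at 729 and 180 CPM, and T-like or NK-like cluster 12 at 743 and 196 CPM. Hnf4a was at 106 CPM in cluster 14 and 27.5 in cluster 16, against 34.4 in B-like cluster 8 and 39.3 in T-like or NK-like cluster 12. The lower identity and bile acid genes thus came with a smaller share of cluster 14 and were not told from it. In these medians a gene with 0 counts on one side stands at its bound. Random lists do not keep the correlation between the members of a list, and each side was 1 library. The place of a median among them is thus no test of the list.

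**Figure D4:**
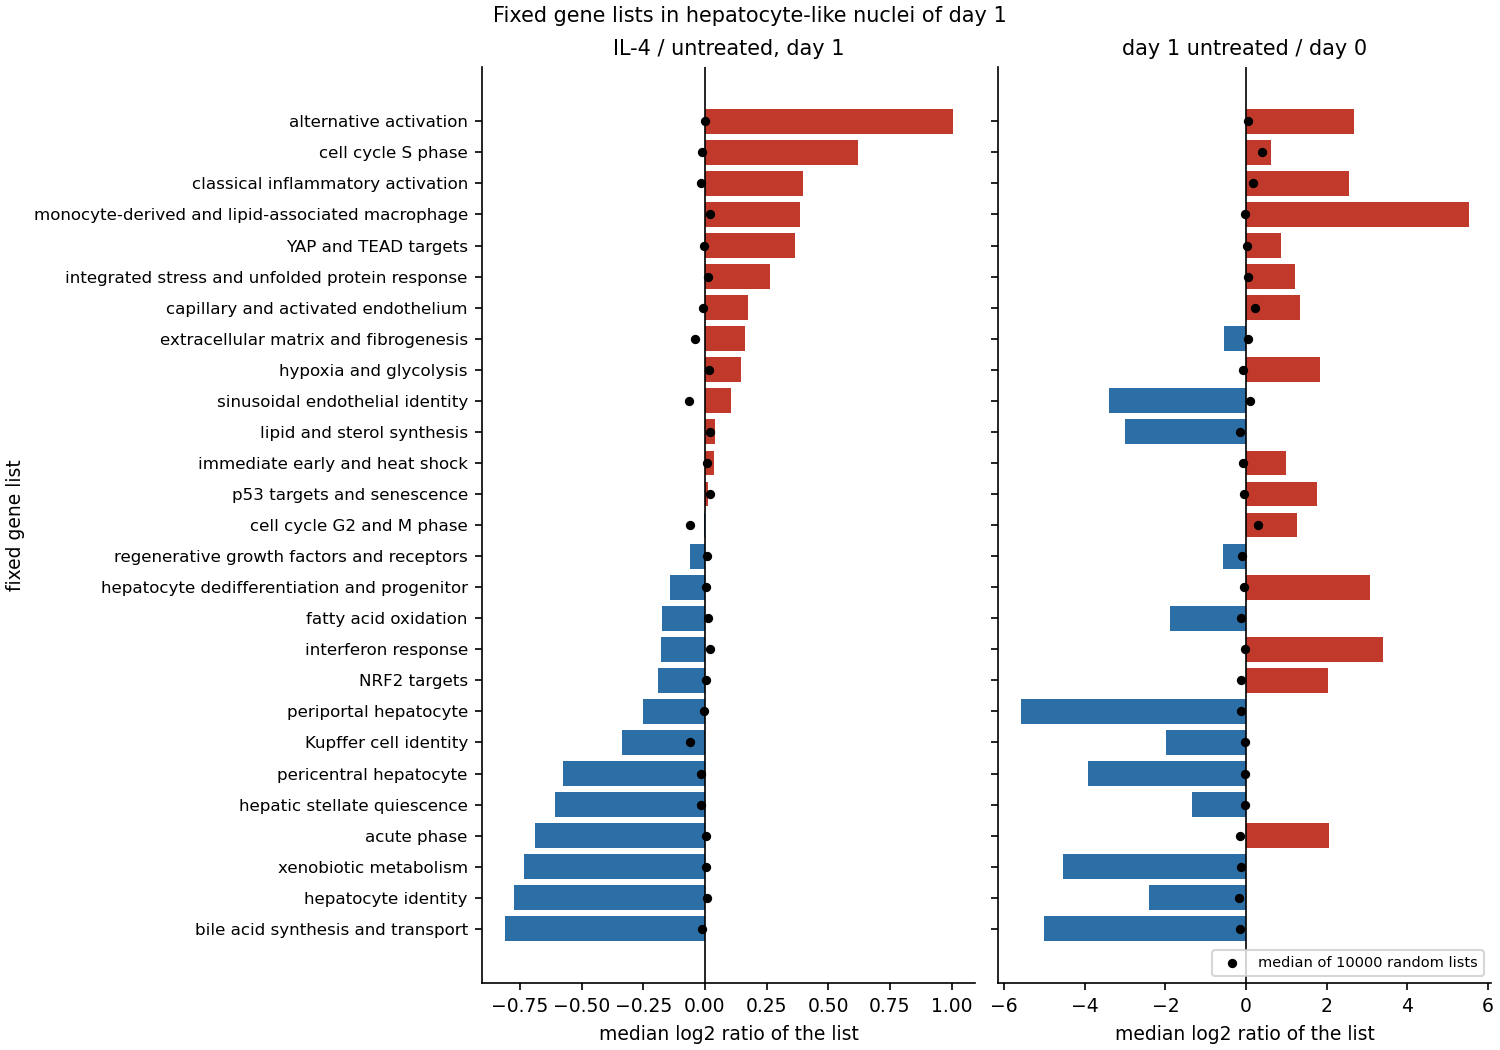
Median log2 ratio of each of 27 gene lists in hepatocyte-like nuclei, for IL-4 over untreated on day 1 and for untreated day 1 over day 0; black dots are the medians of 10000 random lists matched on size and expression. With IL-4 the alternative activation list lies highest (1.01) and the bile acid list lowest (-0.81).

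From day 0 to day 1 without IL-4, the hepatocyte-like class changed far more. Cluster 16, with 492 of its 1207 untreated day 1 nuclei, held Hnf4a at 27.5 and Alb at 576 CPM (plain totals). B-like cluster 8 held them at 34.4 and 598 CPM, and T-like or NK-like cluster 12 at 39.3 and 553 CPM. A change within hepatocytes was thus not told from a change in what the class held. The urea cycle gene Cps1 went from 9371 to 4.87 CPM (scaled by trimmed means, as are all CPM of classes in this part), the tyrosine aminotransferase Tat from 3074 to 5.77 CPM and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 493 to 0.509 CPM. The progenitor and biliary genes Sox9 and Spp1 went from 4.68 to 198 CPM and from 9.51 to 855 CPM. Free RNA was not excluded for these 2, as B-like cluster 8 and T-like or NK-like cluster 12 held Sox9 at 162 and 165 and Spp1 at 660 and 608 CPM (plain totals, most nuclei being of day 1). All 17 bile acid genes were lower (median -5.00), as were 17 of 18 periportal genes (median -5.60), 21 of 22 xenobiotic metabolism genes (median -4.55) and all 18 genes of lipid and sterol synthesis (median -3.00). Higher were all 16 interferon genes (median 3.41), 14 of 15 NRF2 targets (median 2.04), 13 of 15 dedifferentiation genes (median 3.08) and 14 of 18 acute phase genes (median 2.07). The largest median rise of the 27 lists was that of monocyte-derived and lipid-associated macrophages, with 8 of 9 genes higher (median 5.53). Of 15 alternative activation genes 10 were higher (median 2.67). Each of these medians lay outside all 10000 random lists, which as above is no test of the lists. The day 1 slices also differed from day 0 in sex and depth. Free RNA was not excluded for the lists that rose. Interferon genes were among those leading cluster 19, of 91 untreated day 1 nuclei.

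Macrophage-like and endothelial-like nuclei also changed with culture, in a contrast of days 1, 3 and 5 with the single day 0 library. That library was assumed to vary like the others, so the p-values and counts here cover no spread between day 0 slices or animals and do not part culture from depth. In macrophage-like nuclei 9 of 15 Kupffer cell genes fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 4.01e-25, and adjusted p = 0.154 with an estimated correlation). The prostaglandin dehydrogenase Hpgd fell by 6.68 and the class II antigen presentation genes H2-Eb1 and H2-Aa by 7.18 and 6.55. Of 11 genes of monocyte-derived and lipid-associated macrophages, 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 1.41e-17, and adjusted p = 0.154 with an estimated correlation). The lysosomal glycoprotein Gpnmb and the collagenase Mmp13, both at 0 counts on day 0, were at least 164-fold and at least 163-fold higher. In endothelial-like nuclei 13 of 16 sinusoidal genes fell and 0 rose (16 and 0 adjusted over the list alone; camera adjusted p = 9.63e-47, and adjusted p = 0.109 with an estimated correlation), with the nuclease Dnase1l3 down by 7.31 and the elastin gene Eln by 8.60. Nav3 and Slc8a1, at 0 counts on day 0, were at least 49.7-fold and at least 65.0-fold higher. The counts were 438 higher and 746 lower in macrophage-like nuclei, and 470 and 707 in endothelial-like nuclei, 1177 in all against 568 without the day 3 libraries and 1790 without those of day 5. Of the hepatocyte identity genes, 7 of 14 fell and 0 rose in macrophage-like nuclei (10 and 0 adjusted over the list alone; camera adjusted p = 2.18e-10, and adjusted p = 0.390 with an estimated correlation), and 6 of 16 fell and 0 rose in endothelial-like nuclei (9 and 0 adjusted over the list alone; camera adjusted p = 1.14e-11, and adjusted p = 0.472 with an estimated correlation). Hepatocyte transcripts were abundant in the empty barcodes of day 0, with Pck1 at 3834 and Cps1 at 4557 CPM.

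Summed over all nuclei of a slice, which mixes changes within cells with changes in their shares, 142 genes were higher and 57 lower with IL-4, 199 of 20320. Nts rose by 6.40 (SE 0.63, adjusted p = 0.0325), Slc7a2 by 3.53 (SE 0.21, adjusted p = 0.0242), Ptgs2 by 3.54 and Esm1 by 2.28, and Retnla (0 and 462 counts) was at least 149-fold higher. Lower were Hgf by -1.88, the biliary gene Pkhd1 by -1.38 and Nr1h4 by -1.10. Of 25 alternative activation genes, 11 rose and 0 fell (22 and 0 adjusted over the list alone; camera adjusted p = 9.17e-40, and adjusted p = 0.119 with an estimated correlation). No camera call in any comparison held with an estimated correlation. Without the libraries of day 3 or of day 5, and without a term for day, edgeR called 0 genes (2649, 2451 and 727 at an unadjusted p under 0.05), and DESeq2 on all libraries called 1426. The count was 1071 without the day 1 libraries and 597 without the day 3 nuclei that had Xist and no Y-linked transcripts. Il2rg, the common gamma chain of the type I receptor, was listed at 0 in every class and library, lymphocytes included, so a gene missed in the counting upstream was not told from one not expressed.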

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

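The tests of technical explanations below were chosen after the results were seen. An interaction test for a difference in the IL-4 effect between classes called 184 genes between macrophage-like and endothelial-like nuclei, 168 between macrophage-like and cholangiocyte-like nuclei and 170 between endothelial-like and cholangiocyte-like nuclei. Among listed genes, the inhibitory Fc receptor Fcgr2b and the mannose receptor Mrc1 had IL-4 effects 6.23 (adjusted p = 0.00475) and 5.51 (adjusted p = 0.00744) higher in macrophage-like than in endothelial-like nuclei, and were higher in the former and lower in the latter on every day. The cadherin Cdh1 (4.25, adjusted p = 0.0228) and the basement membrane collagen Col4a1 (-2.09, adjusted p = 0.0293) also had opposite signs on every day between these 2 classes, though neither effect was called in endothelial-like nuclei (adjusted p = 0.0504 and 0.119). Hbegf (1.78, adjusted p = 0.0208) and Ch25h (2.82, adjusted p = 0.0208) had larger effects in macrophage-like nuclei, with the same direction in both. Between macrophage-like and cholangiocyte-like nuclei, the adhesion molecule Vcam1 (-1.31, adjusted p = 0.0147) and Col4a1 (-2.29, adjusted p = 0.0163) had opposite signs on every day, though Vcam1 was not called in the former (adjusted p = 0.0507) nor Col4a1 in the latter (adjusted p = 0.0733). Between endothelial-like and cholangiocyte-like nuclei, Top2a (-2.37, adjusted p = 0.0469) and the epithelial adhesion molecule Epcam (-2.20, adjusted p = 0.0162) did so, though neither effect was called in endothelial-like nuclei (adjusted p = 0.0714 and 0.0712), nor was Top2a in cholangiocyte-like nuclei (adjusted p = 0.126). In the empty barcodes Epcam went from 112 to 119 CPM on day 1, from 406 to 184 CPM on day 3 and from 1600 to 1003 CPM on day 5; free RNA as the source of its fall in endothelial-like nuclei was not tested. No biological explanation for these differences was tested.

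In barcodes taken as empty, which no comparison of the report tests, Chil4 was at 944, 4844 and 42965 CPM with IL-4 on days 1, 3 and 5, against 71.3, 6.63 and 0.478 CPM untreated, and on day 5 it was the most abundant gene of the empty barcodes. For Chil4 in macrophage-like, endothelial-like and mesenchymal-like nuclei, free RNA from epithelial nuclei was neither shown nor excluded as the source. In 8 of 8 pairs of class and IL-4 library its share of the empty level was at or below that of the median cholangiocyte marker. In macrophage-like nuclei it was 6.65%, 1.74% and 2.07% of the empty level on days 1, 3 and 5, against 8.59%, 3.65% and 8.73% for that marker. The median takes in markers these classes may express themselves, and against the lowest marker Chil4 was at or below it in 2 of 8 pairs. On day 5 it lay at 2.07%, 0.792% and 0.777% in macrophage-like, endothelial-like and mesenchymal-like nuclei, above Epcam at 0.497%, 0.371% and 0.501%. In endothelial-like and mesenchymal-like nuclei, Chil4 counts exceeded Chil3 counts in 5 of 5 pairs. Reads of the paralog Chil3 counted as Chil4 could give this only if most Chil3 reads were counted so. In macrophage-like nuclei of day 3 most were not, with 256 Chil4 against 2673 Chil3 counts. The counts of the endothelial-like and mesenchymal-like nuclei alone do not exclude the paralog. In macrophage-like nuclei that explanation stayed open too, with more Chil4 than Chil3 in 1 of 3 libraries. No biological explanation was tested.

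In the IL-4 library of day 3, 2.05% of nuclei had Xist and no Y-linked transcripts, against 0.216% in the untreated library of that day, while most nuclei of both had Y-linked transcripts and no Xist (90.8% and 91.6%). Free Xist RNA was excluded, since 82.9% of hepatocyte-like nuclei (34 of 41; interval 67.9 to 92.8) had this pattern against 0.438% (9 of 2053; 0.201 to 0.831) of the others. They differed from the kept day 1 nuclei: Cps1 was at 4244 CPM in the 34 hepatocyte-like nuclei, against 5.41 and 3.93 CPM in untreated and IL-4 hepatocyte-like nuclei of day 1 and 7427 CPM on day 0 (CPM of plain totals here). The median of the 34 nuclei was 5174.5 UMIs, under the day 1 minimums of 5661 and 6054 UMIs. Day 1 barcodes under those minimums were not compared, so the day 1 libraries were not excluded as the source. The origin of these nuclei remained open, nuclei of another female animal were not told apart, and no biological explanation was tested. They were 34 of the 41 hepatocyte-like nuclei of that library, so the hepatocyte-like share of 1.96% was 0.341% without such nuclei.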

How the results depend on the processing

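Libraries were matched by day through the term for day; the labels give no replicate numbers to pair by. Of 2285 values of named genes under alternatives, 1959 kept direction and side of the threshold, 315 kept direction and lost the call, and 11 changed sign; of 136 counts and shares, 84 held and 52 moved. Of the 315 calls lost, 153 were lost without a term for day, 31 each without day 3 and without day 5, and 28 with the mixed clusters counted; the cause was not tested. RLE scaling moved the share of higher calls by at most 10 points. DESeq2, with its own size factors, gave 859 higher and 567 lower in all nuclei, against 142 and 57, and 209 and 501 with culture in endothelial-like nuclei, against 470 and 707. Not run: tests and lists in hepatocyte-like nuclei, which fell under 20 nuclei in the untreated library of day 3 and both of day 5, leaving out days in mesenchymal-like nuclei and the epithelial clusters, which leaves no residual degree of freedom, and a minimum of 1000 UMIs, which removed nothing. The culture contrast of endothelial-like nuclei was not run in the deepest 2000 nuclei, where the day 0 library fell under 20 of them.

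The counts of genes called were 726 in macrophage-like, 731 in endothelial-like, 110 in mesenchymal-like and 560 in cholangiocyte-like nuclei, 1401 in the epithelial clusters and 199 in all nuclei with IL-4, and 1177 and 1184 with culture in endothelial-like and macrophage-like nuclei. DESeq2 gave 453 in macrophage-like, 441 in endothelial-like, 269 in cholangiocyte-like, 539 in the epithelial clusters, 1426 in all nuclei, and 710 and 696 with culture. With no low-count filter the counts were, in the order above, 1582, 1689, 925, 1006, 2182, 529, 1894 and 2129. Without a term for day edgeR gave 49 in macrophage-like, 1 in endothelial-like and 6 in cholangiocyte-like nuclei, and 0 in mesenchymal-like nuclei, the epithelial clusters and all nuclei (468, 1041 and 727 at an unadjusted p under 0.05; DESeq2 was not run without the term). In mesenchymal-like nuclei the count was 199 with RLE scaling, 18 without the 200 most abundant genes of empty barcodes, 245 at a mitochondrial ceiling of 1%, 558 with doublets kept and 317 at a doublet score of 0.25. That score gave 868 in the epithelial clusters and 329 in all nuclei, and doublets kept gave 317 in all nuclei. The deepest 2000 nuclei gave 1026 in cholangiocyte-like nuclei, where the day 1 libraries also dropped out (10 untreated nuclei; 803 without day 1 alone), and 302 with culture in macrophage-like nuclei, a ceiling of 1% gave 711 with culture in endothelial-like nuclei, counting the mixed clusters gave 272 in macrophage-like nuclei, and leaving out Xist-positive day 3 nuclei gave 597 in all nuclei. Leaving out 1 day at a time gave 290 to 977 in macrophage-like, 139 to 883 in endothelial-like and 351 to 803 in cholangiocyte-like nuclei, and 0 to 1071 in all nuclei (0 without day 3 and without day 5, with 2649 and 2451 at an unadjusted p under 0.05). With culture it gave 568 to 1790 in endothelial-like and 960 to 1641 in macrophage-like nuclei.

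The changes of sign were all in Il4ra, Il13ra1 or Stat6, with no call. Endothelial Il4ra was 0.0226 with no filter and 0.0546 at a minimum of 2000 UMIs, and -0.16 (without day 5) to 0.13 (without day 1) with 1 day left out. Likewise endothelial Il13ra1 ran from -0.85 (without day 5) to 0.0574 (without day 3) and Stat6 from -0.10 (without day 5) to 0.20 (without day 3). In mesenchymal-like nuclei Stat6 was 0.0859 at a ceiling of 1% and 0.21 at 2000 UMIs, where day 1 came in. In cholangiocyte-like nuclei Il13ra1 was -0.0724 at 2000 UMIs and -0.13 (without day 3) to 0.18 (without day 5) with 1 day left out, macrophage Il13ra1 was -0.12 (without day 5) to 0.43 (without day 1), and epithelial Stat6 was -0.0471 without a term for day. The hepatocyte-like share of day 0 was 98.6% in the deepest 2000 nuclei, 87.6% at a ceiling of 1% and 91.1% at 2000 UMIs. At a ceiling of 1% it was 43.7% and 33.4% in the untreated and IL-4 libraries of day 1 and 0% untreated on day 5, and at 2000 UMIs it was 43.9% untreated on day 1. Untreated on day 3 it was 1.34% with doublets kept and at a score of 0.25, and with IL-4 on day 3 it was 0.341% without Xist-positive nuclei.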

Other observations

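The tests of cluster 17 and of other splits below were chosen after the results were seen. Macrophage-like nuclei showed less of the G2 and M programme with IL-4 on day 5. After thinning, 25.5% (17.4 to 35.1) of untreated and 7.83% (3.64 to 14.3) of IL-4 macrophage-like nuclei counted on day 5, and 28.98% and 22.5% on day 3 (unthinned 57.8% and 35.7% on day 5, and 40.9% and 46.2% on day 3). Their median depths were 9501.5 and 8857 UMIs on day 5, and 3972 and 5544 on day 3. Mesenchymal-like nuclei gave 38.1% and 25.1% on day 3 and 17.4% and 19.2% on day 5 (unthinned 52.9% and 47.4%, and 41.5% and 32.2%), at median depths of 5220 and 6107 UMIs on day 3 and 9209 and 7039 on day 5. Endothelial-like nuclei gave 1.18% and 3.45% on day 3 and 6.59% and 1.24% on day 5. These are values of single libraries with no test. B-like nuclei were 4.80% of IL-4 nuclei on day 1, against 5.34% untreated, with 0.287% on day 3 and 0.0938% on day 5 in the IL-4 libraries and 0.224% on day 0; T-like or NK-like nuclei were 2.25% with IL-4 on day 1, 1 of 2094 on day 3 and 0 of 2132 on day 5, and 0.160% on day 0. In the empty barcodes of day 0 the most abundant genes were Cmss1 (35854 CPM), Malat1 (29374 CPM), Gm42418 (18072 CPM), AY036118 (14915 CPM) and mt-Co1 (10884 CPM), and the osteopontin gene Spp1 was among the first 5 on day 5.

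Cluster 17, of 235 untreated and 377 IL-4 nuclei of day 1, held macrophage and hepatocyte transcripts together and was left unnamed. Free hepatocyte RNA in macrophage nuclei stayed open: hepatocyte markers were 6.63 times (untreated) and 2.78 times (IL-4) as high as in macrophage-like nuclei of the same library, but 0.775 and 0.862 times as high as in the highest other named class, B-like nuclei untreated and T-like or NK-like nuclei with IL-4. Droplets or clumps holding nuclei of both types could account for its depth: the median was 110.9% (untreated) and 100.7% (IL-4) of the sum of the 2 class medians, at 22010 and 18817 UMIs against sums of 19852 and 18683.5. Macrophage markers, though, were at 17.2% and 21.3% of the macrophage-like level. Macrophage-like medians were 9001 and 8401.5 UMIs, so 1 nucleus of each type would leave a larger share. B-like cluster 8 and T-like or NK-like cluster 12 were deep as well, at medians of 14080 and 14072 UMIs. Such droplets were neither shown nor excluded. No biological explanation was tested.

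The 6 cultured libraries make 10 splits into groups of 3, too few for a share under 0.05, and some of them do not part the pair of every day. In macrophage-like nuclei the split by IL-4 called 726 genes and the highest other split 0, in endothelial-like nuclei 731 and 0, in cholangiocyte-like nuclei 560 and 13, and in all nuclei 199 and 0, so that 1 split of the 10 reached the count in each. The other splits either part the pair of 1 day only or swap the IL-4 label of 1 day. Both put an IL-4 effect into the residual spread of the model. Low counts there follow largely from the design, so the splits do not speak for or against chance.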
